A study of Mus musculus with 119 samples.

How the data were processed

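RNA was sequenced from satellite cells, the muscle stem cells, sorted from resting limb muscle of mice. Per the labels and the series description, dissociated muscle was depleted of cells bearing CD45 (leukocytes), CD31 (endothelium) or Sca-1 (fibro-adipogenic and endothelial cells). Cells positive for α7-integrin and CD34 were collected, and RNA was taken directly after the sort. In 4 of the 10 experiments used here the cells were further parted by the amount of CD34 on their surface.

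The series lists 119 samples in 13 experiments. Of these, 10 experiments have a table of deposited counts, that is raw read counts per gene symbol for 24421 symbols, with no scaling by the submitters. Whole numbers from 0 with totals that differed between libraries were checked in every table. Per the submitters' processing notes, bcl2fastq 2.17.1, Trim Galore, TopHat2 2.1.1, Partek 7.0 and HTSeq were used with the mouse genome build mm10. Their order, the gene annotation and the counting options are not given in the sources used here. In the tables of experiments 5, 7 and 8, 12 genes carry names changed into dates, and these genes could not be matched between tables.

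The 80 libraries used were placed in groups by the labels alone. The 36 samples of experiments 11 to 13 were not analysed here. In experiment 5 the table holds 4 WT columns for 3 labelled WT samples, and no label says which column belongs to which sample. Those 4 columns and the 3 labelled samples were not used here, so that the comparison of KO with WT at 8 days was not run. In experiment 4 the table names the gates High, Low and Neg, while the labels name them CD34Hi, CD34Med and CD34Lo. They were matched in order of CD34 level. In experiment 2 the labels call the later age adult while the title of the table calls it old, and adult is used here. Young, adult, old and geriatric are given without a number of months in most labels.

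Total counts per library ran from 4.13 M to 78.09 M. None of the 105 pairs of libraries within a group agreed within sampling noise (lowest chi-square per degree of freedom 8.37), so each library counts as 1 sample. Pairs within the groups of experiment 1 had correlations of log2 counts of 0.671 to 0.774 (geriatric) and 0.877 to 0.935 (young). In experiment 2, young CD34Lo replicate 4 had 0.808 to 0.829, and the other pairs of its group 0.953 to 0.964. The labels do not say whether the samples of a group came from separate animals, so p-values measure the spread between these samples, which could be partly technical.

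Each experiment was fitted on its own in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups (minimum count 10, minimum total 15), libraries were scaled by TMM, and groups were compared by the quasi-likelihood F-test with 1 dispersion trend for all libraries of the experiment. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, with a threshold of 0.05. In all, 19 comparisons were fitted, including 2 interactions of age with CD34 gate. Levels are CPM, counts over the TMM-scaled total of the library in units of M, given as mean ± SD, and log2 fold changes come from the fit with their standard error (SE). Gene positions are those of the GENCODE mouse annotation on mm10.

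The design, the groups, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The 19 gene lists covered quiescence-associated satellite cell genes, the Notch pathway, myogenic commitment and early differentiation, mature myofibre, cell cycle, immediate early and dissociation stress genes, FoxO target genes, the IGF, PI3K and Akt pathway, senescence and secretory phenotype, and extracellular matrix and adhesion of satellite cells. They also covered markers of fibro-adipogenic cells and fibroblasts, endothelium, immune cells, pericytes and smooth muscle, Schwann and neural cells and red blood cells, as well as oxidative phosphorylation, cytosolic ribosomal proteins, and interferon response and antigen presentation. Lists overlap in part, since Cd34, Gpx3 and others stand in more than 1 of them and several markers of other cell types are also expressed by satellite cells. Each list with at least 5 measured members was tested with camera of limma 3.58.1, which asks whether a list moved more than the other genes. The correlation between genes was preset at 0.01 and, in a second run, estimated from the data. Values were adjusted over the lists of a comparison. Members past the threshold were counted over all genes tested and again adjusted over the list alone. The red blood cell list had fewer than 5 measured members in every comparison and gave no test.

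Named genes were taken by a rule. In the main comparisons they were the 8 genes with the largest rise and the 8 with the largest fall, and in the other comparisons the 3 largest each way. They had to pass the threshold, average at least 8 CPM and show no overlap between the groups. Predicted, mitochondrial, ribosomal protein, small RNA and antisense genes were left out. For each list past the threshold, the 4 members with the smallest adjusted p that moved in the direction of the list were added. Cd34, Pax7, Foxo1, Foxo3, Foxo4, Spry1, Calcr, Hes1, Heyl, Myf5, Myod1, Myog, Cdkn1b and Mki67 were taken in every comparison.

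A signature of the CD34 gates was drawn from experiment 4 (96 genes higher and 17 lower in CD34Lo than in CD34Hi) and tested with camera in the comparisons of the other experiments, which share no library with it. Overlaps of called genes between experiments were tested with a one-sided Fisher's exact test, adjusted over the pairs of experiments and both directions.

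The alternatives were DESeq2 1.42.0 with its own size factors, RLE scaling, no filter on low counts, only the libraries of the groups compared, and leaving out each library in turn. An estimated correlation, a smaller signature and library numbers as a replicate block were also tried. Where the correlation of libraries with the same number was above 0.1 in every pair, as for CD34Lo and CD34Hi of geriatric cells in experiment 1 and of experiment 4, the blocked count is given beside the result. Alternatives chosen after the data were seen left out the geriatric libraries that hold Xist at 50 CPM or more, used column numbers as a replicate block in experiments 4 and 7, or left out Malat1 and Rn45s.

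The procedure was tested on simulated counts. These were drawn from negative binomial distributions with the mean and dispersion of each gene over all libraries of an experiment, with 100 genes changed 2-fold and 100 changed 8-fold between the groups compared. Differences between real libraries beyond this model were not simulated. At the sizes of the 9 designs tried, edgeR recovered 87 to 100 of the 8-fold genes with the right sign and 2 to 62 of the 2-fold genes, with 4 to 15 false calls among all genes. DESeq2 recovered 93 to 100 and 20 to 74 of them, with 18 to 79 false calls. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.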

Results

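The 80 libraries fell into 10 experiments. Experiments 1 to 4 compared cells with high surface CD34 (CD34Hi) with cells with low CD34 (CD34Lo). Experiment 1 held 4 libraries of each gate from young and from geriatric wild-type (WT) mice. Experiment 2 held 4 young CD34Hi, 4 young CD34Lo, 3 adult CD34Hi and 4 adult CD34Lo libraries, and experiment 3 held 3 young CD34Hi and 2 young CD34Lo libraries. Experiment 4 held 4 libraries each of CD34Hi, CD34Med and CD34Lo from Pax7-ROSAYFP mice, in which cells of the Pax7 lineage carry a fluorescent label. Experiments 5 to 10 compared cells of mice labelled as lacking FoxO1, FoxO3a and FoxO4 (KO) with WT cells without a split by CD34. They held 6 KO libraries at 8 days, 4 KO and 3 WT at 21 days, 2 KO and 2 WT of young Pax7-ROSAYFP mice, 2 KO and 3 WT of young mice, 2 KO and 2 WT of old mice, and 3 KO and 3 WT of old mice at 22 months.

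Total counts per library were 6.27 M to 16.11 M in experiment 1, 4.16 M to 8.91 M in experiment 2 and 4.13 M to 7.08 M in experiment 4. They were 38.26 M to 70.46 M in experiment 3 and 16.04 M to 78.09 M in experiments 5 to 10. Counts of amplified low-input libraries are not counts of separate molecules.

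Cd34 lies on chromosome 1 at 194938819 to 194961279 of mm10, and Myog at 134289989 to 134292548. Pax7 lies on chromosome 4 at 139737062 to 139833528, Spry1 on chromosome 3 at 37639947 to 37644598 and Calcr on chromosome 6 at 3685680 to 3764714. Foxo1 lies on chromosome 3 at 52268336 to 52353221, Foxo3 on chromosome 10 at 42181841 to 42276755 and Foxo4 on chromosome X at 101254528 to 101260873. Tnc lies on chromosome 4 at 63959785 to 64047015, Gpx3 on chromosome 11 at 54902453 to 54910377, Actc1 on chromosome 2 at 114047282 to 114053548 and B2m on chromosome 2 at 122147686 to 122153083. All are annotated as protein coding.

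The first question of the series was how cells with high and low CD34 differ. Among lineage-labelled cells of experiment 4, Myog, the transcription factor of myogenic differentiation, stood at 1300 ± 404 CPM (SD, n = 4) in CD34Lo and at 2.6 ± 1.27 CPM (n = 4) in CD34Hi. Actc1, the cardiac actin of early muscle differentiation, stood at 1330 ± 706 and 2.04 ± 1.85 CPM. The acetylcholine receptor subunit Chrnd was at 107 ± 57.5 and 0.28 ± 0.171 CPM, and the embryonic troponin Tnnt2 at 41.8 ± 20.8 and 0.066 ± 0.132 CPM. Lower in CD34Lo were Cd34 itself, which was the sort marker (98.4 ± 41.6 against 493 ± 185 CPM, log2 fold change -2.32), the potassium channel subunit Kcne4 (-2.36) and the IGF binding protein Igfbp4 (-2.04). Pax7 (16.2 ± 9.43 against 21.3 ± 6.34 CPM) and Myod1 (140 ± 19.4 against 130 ± 71.3 CPM) did not pass the test.

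Of the 31 measured genes of myogenic commitment, 16 rose and 0 fell over all genes tested, and 20 rose adjusted over the list alone. The list moved up as a whole (adjusted p = 6.33e-60, and adjusted p = 0.00213 with an estimated correlation). Of the 27 measured genes of mature myofibre, 10 rose, among them Acta1 (1280 ± 388 against 13.7 ± 8.36 CPM), Ttn (474 ± 144 against 8.32 ± 5.85 CPM) and Tpm2 (137 ± 45.4 against 17.2 ± 5.08 CPM). This list moved up as well (adjusted p = 1.64e-40, and adjusted p = 0.00635 with an estimated correlation), with 20 members adjusted over the list alone. Moving down were ribosomal proteins (adjusted p = 5.91e-18, but 0.519 with an estimated correlation) with 0 called, and fibroblast markers (adjusted p = 0.0379, but 0.172 with an estimated correlation, and lost in 3 of 8 omissions, up to 0.103 without CD34Lo replicate 2) with 1 of 24 called. Of 12133 genes tested, 113 passed the threshold, 96 higher and 17 lower in CD34Lo. With libraries paired by column number the count was 215. It ranged from 65 without CD34Hi replicate 1 to 119 without CD34Lo replicate 3. Of the 21 named genes past the threshold, 16 stayed past it whichever library was left out. The exceptions were Thy1, Ccl19, Oxtr, Bmper and Postn, with an adjusted p of up to 0.186 for Ccl19 without CD34Lo replicate 4.

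The middle gate, CD34Med, lay between the others. Myog stood at 403 ± 402 CPM, Actc1 at 414 ± 438 CPM and Acta1 at 384 ± 266 CPM (SD, n = 4), while Cd34 stood at 246 ± 41.1 CPM. Against CD34Hi, 27 genes rose and 0 fell, and 11 of the 31 genes of myogenic commitment were among them (adjusted p = 1.05e-66 for the list, 0.00119 with an estimated correlation). Without CD34Hi replicate 1 the count was 12, and without CD34Med replicate 3 it was 39. Myl1 (adjusted p = 0.0835) and Ttn (0.122) were lost without CD34Hi replicate 1. Between CD34Lo and CD34Med, edgeR called 0 genes, with 458 at an unadjusted p under 0.05 and 6 called by DESeq2. The myogenic commitment list still moved up between them (adjusted p = 2.89e-18, 0.0384 with an estimated correlation), with 10 members up adjusted over the list alone. With 0 called, fibroblast markers moved down (adjusted p = 0.00597, but 0.106 with an estimated correlation, and lost in 2 of 8 omissions, up to 0.0549 without CD34Lo replicate 2). So did endothelial markers (0.00597, but 0.533, and lost in 3 of 8, up to 0.716 without CD34Lo replicate 2). Immune markers did too (0.00383, but 0.573, and lost in 2 of 8, with the direction turned and 0.934 without CD34Med replicate 3).

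In young WT cells of experiment 1 the same direction was seen for a few genes. Myog stood at 112 ± 79.6 CPM in CD34Lo, while the 4 CD34Hi libraries averaged 0.0173 ± 0.0345 CPM (SD, n = 4). Actc1 stood at 106 ± 46 and 0.0557 ± 0.0721 CPM, and the protein kinase A inhibitor Pkia at 40.7 ± 11.7 and 4.54 ± 1.49 CPM. These 3 genes rose (adjusted p = 0.0381 each) and 0 fell of 12163 genes tested. DESeq2 called 21, and with only the libraries of the 2 groups 27 rose and 9 fell. Cd34, at 33.1 ± 3.18 against 60.4 ± 14.8 CPM, did not pass the test. Of the 24 measured genes of myogenic commitment, 2 rose, and 5 rose adjusted over the list alone (adjusted p = 2.43e-09 for the list, 0.00784 with an estimated correlation). The list of FoxO target genes moved up with none of its 41 members called (adjusted p = 0.00798, 0.0317 with an estimated correlation, and 0.053 without CD34Lo replicate 4). With 0 called, fibroblast markers (adjusted p = 0.00508, but 0.0944 with an estimated correlation) and myofibre genes (0.00508, but 0.393) moved up. So did oxidative phosphorylation (0.000648, but 0.694, and 0.224 without CD34Lo replicate 2). Interferon genes did too (0.0488, but 0.833, and lost in 4 of 8 omissions, up to 0.181 without CD34Lo replicate 2). The 3 calls were lost whichever of the 8 libraries was left out, with an adjusted p of up to 0.591 for Myog without CD34Hi replicate 3, and the count was then 0 each time.

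In young cells of experiment 2, Myog stood at 95.8 ± 9.65 CPM in CD34Lo and 0.485 ± 0.586 CPM in CD34Hi (SD, n = 4). Tmem8c, the gene of the myoblast fusion protein myomaker, stood at 24.4 ± 7.17 CPM in CD34Lo and had no counts in CD34Hi. Actc1 rose by 4.72 on the log2 scale (SE 0.61, adjusted p = 0.00155), while Cd34, the sort marker, fell by 1.37 (SE 0.17, adjusted p = 0.000819) and the receptor gene Calcrl fell by 2.06 (SE 0.39, adjusted p = 0.0352). In all, 15 genes rose and 15 fell of 12857 tested, and DESeq2 called 108. Of the 29 measured genes of myogenic commitment, 5 rose, and 9 rose adjusted over the list alone (adjusted p = 3.88e-18 for the list, 0.000347 with an estimated correlation). With 0 called, endothelial markers (adjusted p = 3.41e-06), fibroblast markers (0.00083, but 0.0717 without CD34Hi replicate 4) and matrix genes (0.000183, but 0.911 without CD34Lo replicate 4) moved down. Each had 0.646 with an estimated correlation. The count ran from 5 without CD34Hi replicate 3 to 75 without CD34Lo replicate 4. Calcrl (adjusted p = 0.137) and Alpl (0.071) were lost without CD34Hi replicate 4, Klhl41 (0.0606) without CD34Hi replicate 3 and Igfbp4 (0.142) without CD34Lo replicate 1. With only the libraries of the 2 groups Cd34 (0.0648), Calcrl (0.378), Alpl (0.367) and Igfbp4 (0.38) were lost, and with the block on library numbers Tmem8c (0.0592), Calcrl (0.273), Alpl (0.157) and Klhl41 (0.0729).

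The deeper libraries of experiment 3 gave Myog at 63.9 ± 40.6 CPM in CD34Lo (SD, n = 2) and 1.16 ± 1.08 CPM in CD34Hi (n = 3). Cd34 stood at 48.1 ± 22.6 and 186 ± 10.3 CPM, and Dcn, the gene of the matrix proteoglycan decorin, at 24.1 ± 1.71 and 185 ± 40.8 CPM. Of 13929 genes tested, 14 rose and 18 fell, against 73 and 188 with DESeq2 and 90 and 247 with no filter on low counts. The myogenic commitment list moved up, with 5 of 31 members called and 10 adjusted over the list alone (adjusted p = 9.91e-12, but 0.598 with an estimated correlation). The fibroblast list moved down, with 3 of 29 members called and 13 adjusted over the list alone (adjusted p = 9.63e-11, but 0.598 with an estimated correlation). Moving up were Schwann and neural markers (adjusted p = 5.93e-05, but 0.598 with an estimated correlation) with 0 of 20 called and 6 up and 2 down adjusted over the list alone. Moving down were immediate early genes (adjusted p = 1.31e-09, but 0.598 with an estimated correlation, and 0.0584 without CD34Lo replicate 1) with 0 called, and quiescence genes (adjusted p = 0.000224, but 0.598 with an estimated correlation) with 2 of 36 up and 2 down. The count was 1 without CD34Hi replicate 1 and 104 without CD34Lo replicate 2, where the lone CD34Lo library is assumed to vary like the CD34Hi libraries. Of the 15 named genes past the threshold only Dcn stayed past it in every omission, and Myog reached an adjusted p of 0.175 and Cd34 of 0.221 without CD34Hi replicate 1.

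**Figure D1:**
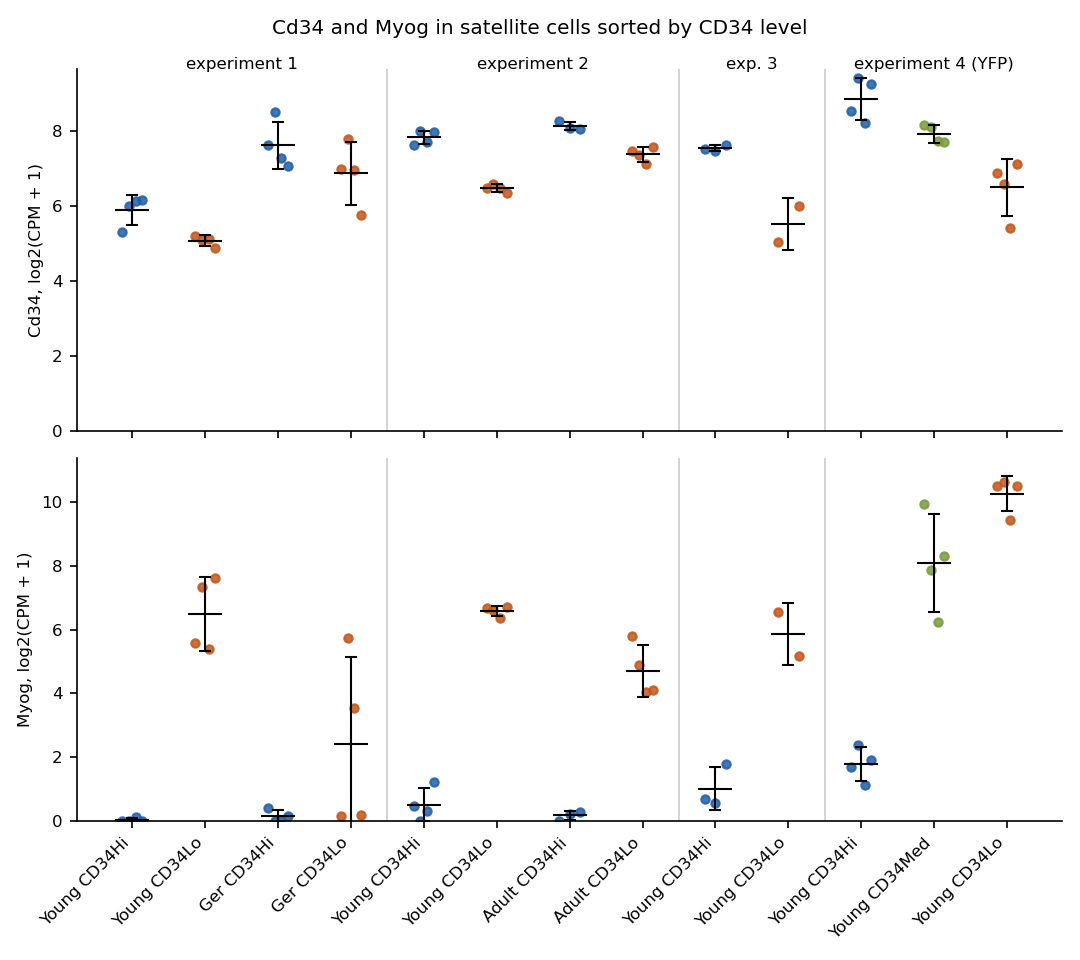
Levels of Cd34 and Myog, log2(CPM + 1), in the sorted gates of experiments 1 to 4, with each point a library, each bar a group mean and each error bar the SD. In experiment 4 Myog averaged 2.6 CPM in CD34Hi, 403 CPM in CD34Med and 1300 CPM in CD34Lo.

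The calls of the 4 young experiments, which share no library, overlapped. Between experiments 2 and 4, 7 genes were higher in CD34Lo in both, against 0.0914 by chance (one-sided Fisher's exact test, adjusted p = 6.48e-12), and between experiments 3 and 4 the number was 9, against 0.104 (adjusted p = 1.04e-15). Myog and Actc1 were the genes shared by experiments 1 and 2 (chance 0.00336, adjusted p = 4.63e-06). Lower in CD34Lo in both experiments 2 and 4 were Cd34, Kcne4, Igfbp4, Gm16897 and Calcrl (chance 0.0204, adjusted p = 2.74e-11). Cd34, Igfbp4, Vtn and Ccl19 were lower in both experiments 3 and 4 (chance 0.0246, adjusted p = 2.1e-08). Cd34 was the sort marker, so that both tests of lower genes were in part fixed by the sort. No gene was called in opposite directions in any pair. Shared genes outside the rule for named genes were chosen after their values were seen.

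In geriatric cells of experiment 1, Myog stood at 15.8 ± 24.9 CPM in CD34Lo and 0.103 ± 0.147 CPM in CD34Hi (SD, n = 4, adjusted p = 0.175), and Cd34 at 131 ± 68.7 and 213 ± 105 CPM (adjusted p = 0.549). Only Slc25a47, chosen after its values were seen, passed the threshold. It had 0 counts in the 4 geriatric CD34Hi libraries and 18 to 80 in the geriatric CD34Lo libraries (adjusted p = 0.0258), with 28 to 108 in the young libraries. DESeq2 called 202 genes, and 1179 had an unadjusted p under 0.05, but 244 of 10768 with only the geriatric libraries (0 called). The myogenic commitment list moved up (adjusted p = 0.0242, but 0.563 with an estimated correlation, and 0.124 without CD34Lo replicate 2), with 0 members called and 3 up adjusted over the list alone. With 0 called, immediate early genes (adjusted p = 0.00317, but 0.7 with an estimated correlation, and lost in 4 of 8 omissions, up to 0.315 without CD34Hi replicate 4) moved up. Ribosomal proteins (adjusted p = 7.86e-15) and oxidative phosphorylation (1.16e-08) moved down, but each had 0.7 with an estimated correlation.

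The geriatric libraries were mixed for Xist, the RNA of the inactive X chromosome in females. Xist stood at 0.312, 0.647, 440 and 418 CPM in geriatric CD34Hi replicates 1 to 4, at 0, 13.5, 377 and 56 CPM in CD34Lo replicates 1 to 4, and at most at 2.76 CPM in the young libraries. Without the 4 libraries at 50 CPM or more, 221 genes parted the geriatric gates, none of the 4 lists above passed (lowest adjusted p = 0.193), and with libraries paired by number the count was 0. It was also 0 without CD34Hi replicate 1 or 4 or CD34Lo replicate 2 or 3, and 2 without CD34Hi replicate 3, 5 without CD34Lo replicate 4, 14 without CD34Hi replicate 2 and 19 without CD34Lo replicate 1.

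In adult cells of experiment 2, Myog stood at 28.6 ± 18.2 CPM in CD34Lo (SD, n = 4) and 0.124 ± 0.111 CPM in CD34Hi (n = 3), and Tmem8c at 11.6 ± 3.46 CPM and no counts. Cd34 fell by 0.75 (adjusted p = 0.0244), from 282 ± 22.7 to 168 ± 22.4 CPM. The stress genes Atf3 (581 ± 167 against 121 ± 14.4 CPM) and Fos (3130 ± 518 against 1030 ± 81.4 CPM) rose, as did the fibroblast markers Dpp4 (168 ± 69.9 against 24.2 ± 3.26 CPM) and Fmod (452 ± 154 against 64.1 ± 41.4 CPM). In all 327 genes rose and 61 fell, and DESeq2 called 811. Of 28 measured fibroblast markers 8 rose, and adjusted over the list alone 9 rose and 2 fell (adjusted p = 0.000116 for the list, but 0.499 with an estimated correlation). Of 46 immediate early genes 7 rose, and adjusted over the list alone 12 rose and 1 fell (adjusted p = 6.37e-05, but 0.499 with an estimated correlation). The myogenic commitment list moved up with 6 members called (adjusted p = 6.37e-05, but 0.062 with an estimated correlation). The count ran from 156 without CD34Hi replicate 3 to 403 without CD34Lo replicate 1. Of 24 named genes 15 stayed past the threshold in every omission, and Cd34 was lost without CD34Hi replicate 1 (adjusted p = 0.144) and with the block on library numbers (0.121).

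The next question was how each gate changes up to geriatric age. In CD34Hi cells the interferon-induced gene Ifit1 stood at 52 ± 51.9 CPM in geriatric and 0.0352 ± 0.0406 CPM in young libraries (SD, n = 4), Iigp1 at 225 ± 214 against 2.56 ± 3.34 CPM and B2m, the light chain of MHC class I, at 6810 ± 3850 against 1220 ± 192 CPM. Cd34 rose from 60.4 ± 14.8 to 213 ± 105 CPM (log2 fold change 1.81, adjusted p = 0.00307), while Spry1, an inhibitor of FGF signalling tied to satellite cell quiescence, fell from 445 ± 68.5 to 147 ± 56 CPM (-1.59, adjusted p = 0.00323) and Myf5 fell from 431 ± 92.5 to 201 ± 45.9 CPM (-1.1, adjusted p = 0.0104). The arginine methyltransferase gene Carm1 (1.29 ± 0.913 against 29.8 ± 12.5 CPM) and the apoptosis gene Bid (2.73 ± 2.2 against 47.3 ± 4.7 CPM) were among the largest falls. Foxo1 did not pass the test (31.4 ± 7.43 against 32.5 ± 3.03 CPM), and Foxo3 and Foxo4 were under 3 CPM in both groups.

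Of 42 measured interferon and antigen presentation genes 28 rose and 0 fell, and 30 rose adjusted over the list alone, with a median log2 fold change of 2.66 (adjusted p = 5.78e-12 for the list, but 0.305 with an estimated correlation). Of 56 cytosolic ribosomal proteins 47 rose and 0 fell, and 52 rose adjusted over the list alone (adjusted p = 4.03e-20, but 0.311 with an estimated correlation). Of 63 genes of oxidative phosphorylation 41 rose and 7 fell, and adjusted over the list alone 44 rose and 7 fell (adjusted p = 2.25e-13, but 0.305 with an estimated correlation). Of 46 immediate early and dissociation stress genes 19 rose and 4 fell (adjusted p = 0.0192, but 0.607 with an estimated correlation, and lost in 2 of 8 omissions, up to 0.093 without geriatric replicate 2). Of 45 matrix genes 10 rose and 3 fell (adjusted p = 0.00977, but 0.392 with an estimated correlation). The quiescence list did not pass (adjusted p = 0.0698), with 10 of 35 members up and 4 down. The shares of counts in the 10 most abundant genes were 13.42 percent in geriatric and 8.26 percent in young CD34Hi libraries. Of 12163 genes tested, 1629 rose and 1229 fell. The count was 1831 without young replicate 2 and 3106 without geriatric replicate 4, and without the Xist-holding geriatric libraries 2396 rose and 2674 fell. Of 43 named genes 39 stayed past the threshold in every omission. The others were Ifi47 (adjusted p = 0.0627 without geriatric replicate 1), Abcc9 (0.0636 without young replicate 1), Cspg4 (0.0552 without young replicate 2) and Calcr (0.11 without geriatric replicate 2, and 0.0505 with only the libraries of the 2 groups).

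In CD34Lo cells B2m stood at 5510 ± 3290 CPM in geriatric and 1200 ± 139 CPM in young libraries (SD, n = 4), the interferon signalling gene Stat2 at 47.6 ± 24 against 5.14 ± 1.94 CPM and the GTPase gene Irgm1 at 545 ± 503 against 31.4 ± 7.35 CPM. Fosb (460 ± 365 against 35.2 ± 12.1 CPM) and Klf4 (346 ± 210 against 54.9 ± 13.1 CPM), both immediate early genes, rose. Cd34 rose from 33.1 ± 3.18 to 131 ± 68.7 CPM (log2 fold change 1.99, adjusted p = 0.00489), Igfbp5 rose by 2.42 (adjusted p = 0.00733) and Cyr61 fell by 2.48 (adjusted p = 0.00577). Myog, at 15.8 ± 24.9 against 112 ± 79.6 CPM, did not pass the test (adjusted p = 0.0985).

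Of the 42 interferon genes 22 rose and 0 fell, and 29 rose adjusted over the list alone, with a median of 2.30 (adjusted p = 7.9e-13, but 0.295 with an estimated correlation). Of the 46 immediate early genes 16 rose and 2 fell, and adjusted over the list alone 28 rose and 2 fell (adjusted p = 6.85e-08, but 0.295 with an estimated correlation). Of 16 pericyte and smooth muscle markers 3 rose, and 5 rose adjusted over the list alone (adjusted p = 0.00392, but 0.295 with an estimated correlation). Ribosomal proteins moved up with 13 of 56 (adjusted p = 6.45e-10, but 0.492 with an estimated correlation), and oxidative phosphorylation with 15 of 63 up and 5 down (adjusted p = 0.000699, but 0.564 with an estimated correlation). Of 45 matrix genes 6 rose and 1 fell (adjusted p = 0.00421, but 0.412 with an estimated correlation, and 0.134 without geriatric replicate 3). The quiescence list moved up, with 6 of 35 members up and 3 down, and 9 up and 3 down adjusted over the list alone (adjusted p = 0.0265, but 0.529 with an estimated correlation, and 0.162 without geriatric replicate 3). The IGF, PI3K and Akt list moved up with 5 of 37 members (adjusted p = 0.0265, but 0.244 with an estimated correlation, and 0.0929 without geriatric replicate 3). It (0.0841) and the matrix list (0.0596) were lost without the Xist-holding libraries. The 10 most abundant genes held 11.58 percent of counts in geriatric and 7.35 percent in young libraries. In all, 975 genes rose and 502 fell. The count was 680 without geriatric replicate 1 and 2858 without geriatric replicate 3, and without the Xist-holding libraries 2057 rose and 2271 fell. Of 49 named genes 29 stayed past the threshold in every omission, and Spry1 (155 ± 83.3 against 347 ± 74.7 CPM, adjusted p = 0.0296) was lost without geriatric replicate 1 (adjusted p = 0.0926) and with only the libraries of the 2 groups (0.0673).

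Whether age acted differently in the gates was tested by the interaction. For this edgeR called 0 genes, with 465 at an unadjusted p under 0.05 and 10 called by DESeq2. The count was at most 1 with any library left out, and 42 without the Xist-holding libraries. The interaction of Cd34 was 0.17 (SE 0.52) and that of Spry1 was 0.43 (SE 0.46) on the log2 scale, so that a difference of age effects between the gates was not detectable for these genes. Among lists with 0 members called, oxidative phosphorylation (adjusted p = 6.1e-13) and ribosomal proteins (adjusted p = 1.52e-10) moved less with age in CD34Lo than in CD34Hi, and both were lost with an estimated correlation (adjusted p = 0.778 each), and ribosomal proteins without the Xist-holding libraries (adjusted p = 0.967). Immediate early genes moved more in CD34Lo (adjusted p = 0.00293, but 0.778 with an estimated correlation, and lost in 4 of 16 omissions, up to 0.227 without geriatric CD34Hi replicate 4). Endothelial markers moved less (adjusted p = 0.0317, but 0.778 with an estimated correlation, and lost in 7 of 16 omissions, up to 0.419 without geriatric CD34Hi replicate 1, and 0.0621 without the Xist-holding libraries).

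**Figure D2:**
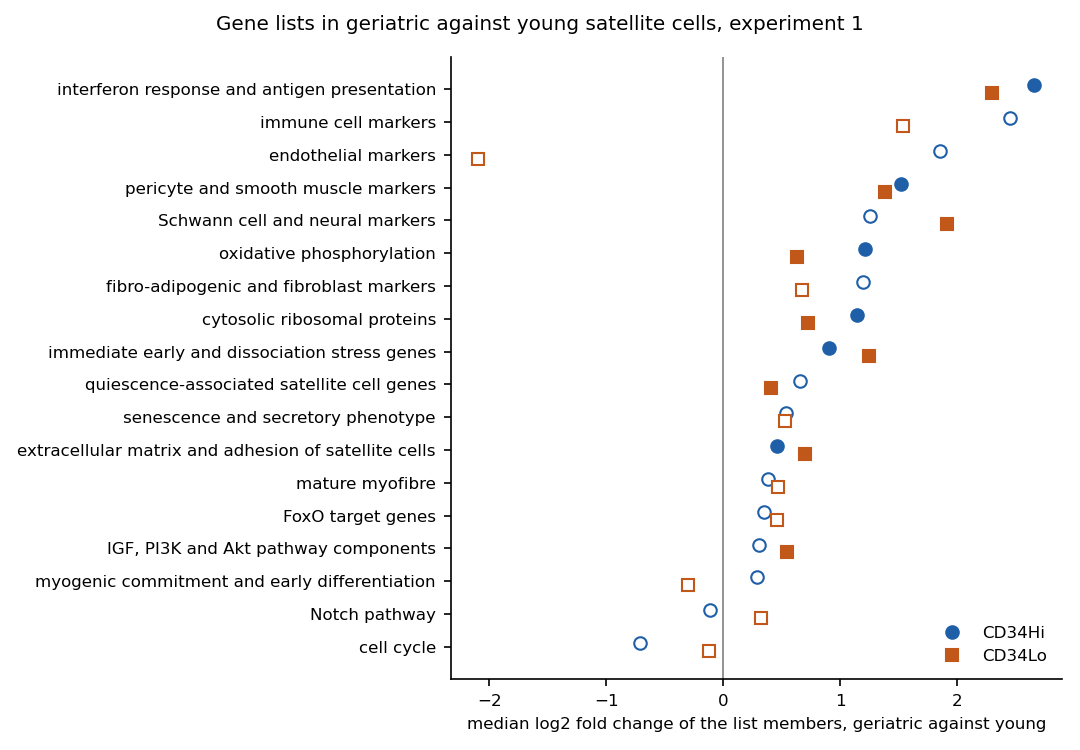
Median log2 fold change of each gene list in geriatric against young cells of experiment 1, circles for CD34Hi and squares for CD34Lo (4 libraries per group), filled where the adjusted p of the list with the preset correlation was under 0.05. With an estimated correlation each filled list had an adjusted p of 0.244 or more. The interferon list had a median of 2.66 in CD34Hi and 2.30 in CD34Lo.

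Adult and young cells were compared in experiment 2. In CD34Hi, Dio2, the enzyme that activates thyroid hormone, rose from 123 ± 15 (SD, n = 4) to 734 ± 54.2 CPM (n = 3), and Cyp26a1, which degrades retinoic acid, rose from 57.9 ± 6.03 to 317 ± 49.6 CPM. Postn fell from 87.8 ± 22.8 to 19.8 ± 8.81 CPM and the heat shock gene Dnajb1 from 500 ± 95.1 to 157 ± 28.2 CPM. Cd34 (282 ± 22.7 against 230 ± 28.8 CPM) did not pass the test (adjusted p = 0.7). Of 42 FoxO target genes 0 were called, and 3 fell adjusted over the list alone, while the list moved down (adjusted p = 1.22e-06, and 0.0038 with an estimated correlation). The endothelial list moved down with 0 called and 13 of 25 down adjusted over the list alone (adjusted p = 1.64e-18). Immediate early and dissociation stress genes moved down with 1 of 46 called and 11 down adjusted over the list alone (adjusted p = 4.21e-12). Myofibre genes moved down with 1 of 29 called and 4 adjusted over the list alone (adjusted p = 9.44e-11). The Schwann and neural list moved down with 1 of 19 called and 5 adjusted over the list alone (adjusted p = 2.03e-09). From the endothelial list on, each had 0.0689 with an estimated correlation. The fibroblast list moved down with 1 of 28 called and 3 adjusted over the list alone (adjusted p = 1.72e-07, but 0.1 with an estimated correlation). In all 13 genes rose and 14 fell, against 57 and 144 with DESeq2 and 68 and 132 with only the libraries of the 2 groups. The count was 4 without adult replicate 3 and 21 without young replicate 1, and of 8 named genes Dio2 and Cyp26a1 stayed past the threshold in every omission, while Postn (adjusted p = 0.0856) and Dnajb1 (0.117) were lost without adult replicate 3.

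In CD34Lo, the complement gene C4b rose from 24.7 ± 12.5 to 316 ± 97.2 CPM with adult age (SD, n = 4). Dpp4 rose from 30.7 ± 4.57 to 168 ± 69.9 CPM, and Cd34 from 88.8 ± 6.21 to 168 ± 22.4 CPM (log2 fold change 0.92, adjusted p = 0.00606, but 0.069 with only the libraries of the 2 groups). Postn fell from 118 ± 34.9 to 21.7 ± 3.03 CPM. Myog (28.6 ± 18.2 against 95.8 ± 9.65 CPM) did not pass the test (adjusted p = 0.0518). Of 47 interferon genes 5 rose, and 9 rose adjusted over the list alone (adjusted p = 9.19e-09, but 0.249 with an estimated correlation). The myogenic commitment list moved down, with 1 member called, and 1 up and 8 down adjusted over the list alone (adjusted p = 5.27e-05, but 0.0703 with an estimated correlation). The fibroblast list, which holds Dpp4, moved up with 4 of 28 up and 1 down, and 7 up and 2 down adjusted over the list alone (adjusted p = 0.00545, but 0.507 with an estimated correlation). It was lost without adult replicate 4 (adjusted p = 0.0872) or young replicate 1 (0.0553). Myofibre genes moved down with 1 of 29 called and 11 adjusted over the list alone (adjusted p = 9.19e-09, but 0.141 with an estimated correlation), and so did the Schwann and neural list with 3 of 19 called, and 1 up and 4 down adjusted over the list alone (adjusted p = 1.09e-05, but 0.165 with an estimated correlation). Pericyte markers moved down with 0 of 21 called (adjusted p = 0.00545, but 0.141 with an estimated correlation). Immune markers moved up with 0 of 23 called (adjusted p = 0.0101, but 0.6 with an estimated correlation), and were lost without adult replicate 4 (adjusted p = 0.948) or young replicate 1 (0.0807) or 2 (0.164). In all 164 genes rose and 45 fell, and DESeq2 called 535. The count was 114 without adult replicate 4 and 538 without young replicate 4, and of 24 named genes 13 stayed past the threshold in every omission.

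The interaction of age and gate called 62 genes in experiment 2, 61 of them positive, that is with a larger rise or a smaller fall in CD34Lo. Among them were Clec3b (3.55, SE 0.56, adjusted p = 0.00643), Dpp4 (2.84, SE 0.47, adjusted p = 0.00817) and Fbln1 (2.54, SE 0.52, adjusted p = 0.0356), all on the fibroblast list, of which 9 members rose adjusted over the list alone (adjusted p = 2.06e-10 for the list, but 0.29 with an estimated correlation). With 0 called, and 0.624 each with an estimated correlation, endothelial (adjusted p = 5.26e-06), immediate early (0.00162) and interferon genes (1.25e-06) also moved more in CD34Lo. So did immune markers (adjusted p = 0.0403, but 0.691 with an estimated correlation, and lost in 6 of 15 omissions, turned with 0.899 without adult CD34Lo replicate 4). The count was 26 without adult CD34Hi replicate 1, where Fbln1 was lost (adjusted p = 0.164), and 146 without young CD34Lo replicate 4.

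The second part of the series removed FoxO1, FoxO3a and FoxO4. At 21 days each of the 4 KO libraries held Foxo1 at 7.91 to 13.6 CPM and Foxo4 at 4.26 to 5.18 CPM, against 90.9 to 99.3 and 78.5 to 91.4 CPM in the 3 WT libraries. Young libraries of experiment 8 labelled KO held Foxo1 at 9.42 and 9.28 CPM and Foxo4 at 1.59 and 2.23 CPM, against 55 to 71.8 and 32.5 to 39.6 CPM in WT. The groups stood closer in experiment 7, with Foxo1 at 30 and 59.2 CPM in libraries labelled KO against 102 and 82.4 CPM in WT, and in experiment 10, with Foxo1 at 47, 24.4 and 28.8 against 62.1, 51.5 and 32.4 CPM. In experiment 9 a WT library had Foxo4 at 8.67 CPM, near the libraries labelled KO at 5.98 and 6.67 CPM. Foxo3 was not lower in KO in any of the 5 comparisons, with 41.4 ± 13.1 against 25.4 ± 4.47 CPM at 21 days. Counts over a whole gene do not show whether the remaining RNA is functional, since the deleted part of each gene is not given in the sources used here.

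**Figure D3:**
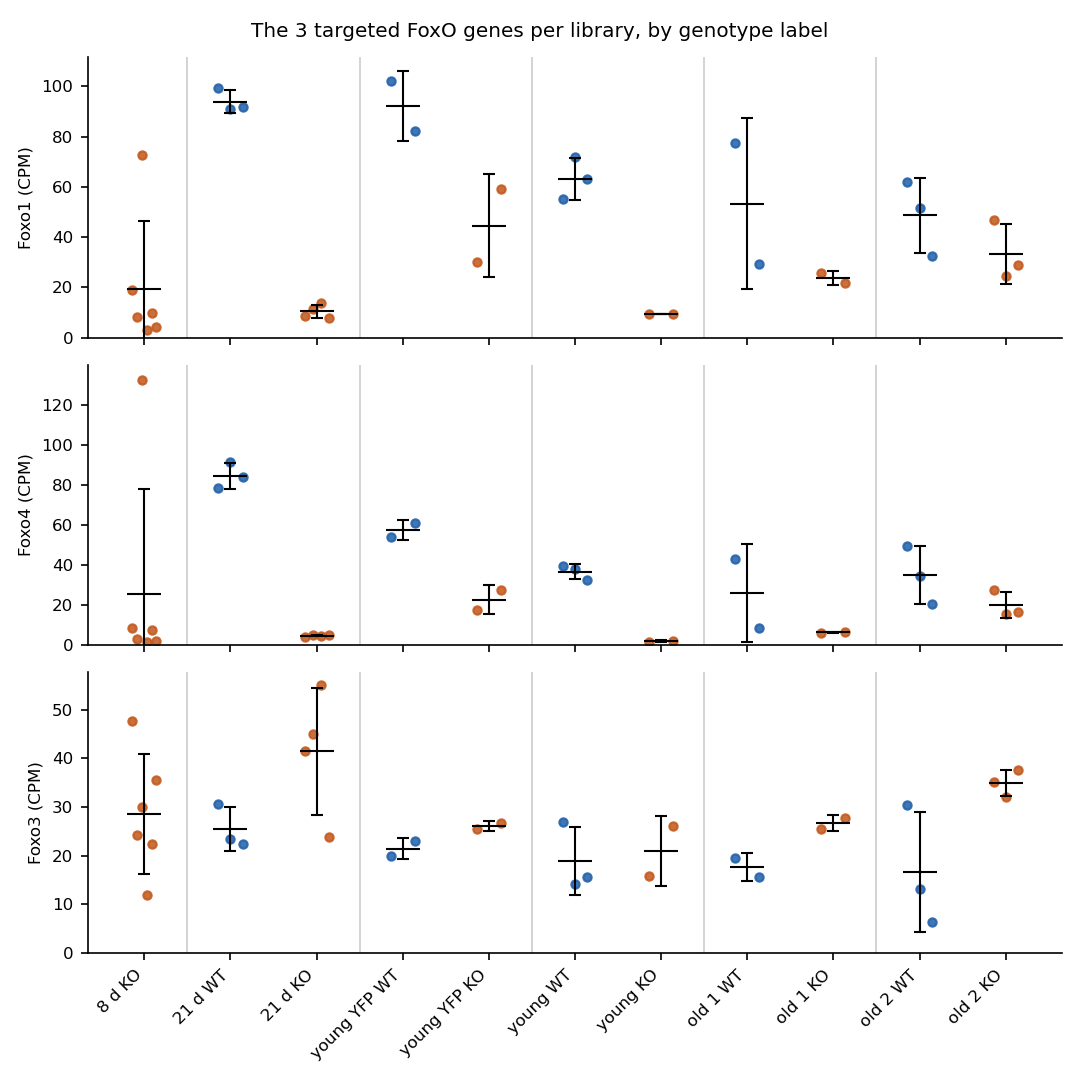
Levels of Foxo1, Foxo3 and Foxo4 in CPM in each library of experiments 5 to 10, with each point a library, each bar a group mean and each error bar the SD. Foxo4 was 4.26 to 5.18 CPM in the 4 KO libraries at 21 days and 78.5 to 91.4 CPM in the 3 WT libraries.

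At 8 days only the KO libraries were used. Foxo1 ran from 2.84 to 72.9 CPM and Foxo4 from 1.68 to 132 CPM over the 6 libraries. Cd34 was 19.1 to 26.2 CPM in 5 of them and 125 CPM in replicate 3, the library labelled KO that also had the highest Foxo1 and Foxo4.

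At 21 days, Cd34 stood at 12.3 ± 1.19 CPM in KO (SD, n = 4) and 192 ± 29.4 CPM in WT (n = 3), a log2 fold change of -3.97 (SE 0.19, adjusted p = 3.67e-07). CD34 was also a sort marker in this experiment. Gpx3, a secreted glutathione peroxidase, stood at 56.9 ± 9.68 and 1160 ± 321 CPM (-4.35, SE 0.24, adjusted p = 1.24e-06), Spry1 at 139 ± 24.8 and 457 ± 95.9 CPM (-1.72, SE 0.21, adjusted p = 0.00126) and Calcr, the calcitonin receptor of quiescent satellite cells, at 116 ± 20 and 279 ± 33.2 CPM (-1.27, SE 0.19, adjusted p = 0.00389). Myog rose from 306 ± 44.7 to 787 ± 200 CPM (1.36, SE 0.23, adjusted p = 0.00864), the embryonic myosin Myh3 from 3.42 ± 0.502 to 13.7 ± 0.564 CPM and Dcx, the gene of doublecortin, from 6.86 ± 1.72 to 67.1 ± 21.9 CPM. Tnc, the gene of the matrix protein tenascin C, rose from 113 ± 14.6 to 495 ± 169 CPM. Pax7 (85.6 ± 35.5 against 178 ± 69.1 CPM), Myod1 and the proliferation gene Mki67 (215 ± 63.2 against 175 ± 56.3 CPM) did not pass the test.

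Of 36 quiescence genes 8 fell and 1 rose, and adjusted over the list alone 15 fell and 2 rose (adjusted p = 1.23e-12, but 0.0587 with an estimated correlation). Of 32 genes of myogenic commitment 12 rose and 0 fell, and adjusted over the list alone 16 rose and 2 fell (adjusted p = 1.21e-14, and 0.0348 with an estimated correlation). Of 34 myofibre genes 6 rose and 1 fell, and adjusted over the list alone 17 rose and 1 fell (adjusted p = 9.7e-16, and 0.00545 with an estimated correlation). FoxO target genes moved down, with Pik3ip1, Igf1r and Gabarapl1 down and 2 of 43 up, and 2 up and 8 down adjusted over the list alone (adjusted p = 0.00151, but 0.501 with an estimated correlation). The fibroblast list moved down with 3 of 29 members, and 14 fell adjusted over the list alone (adjusted p = 7.17e-09, but 0.441 with an estimated correlation). The endothelial list moved down with 1 of 25 members, and 8 fell adjusted over the list alone (adjusted p = 7.17e-07, but 0.47 with an estimated correlation). Moving down with at most 1 called were immune (adjusted p = 0.0226, but 0.837 with an estimated correlation, and lost in 2 of 7 omissions, up to 0.819 without WT replicate 2), pericyte (adjusted p = 0.0345, but 0.837 with an estimated correlation, and 0.182 without WT replicate 1) and Schwann markers (adjusted p = 0.0182, but 0.837 with an estimated correlation, and 0.494 without WT replicate 1). The last 2 were also lost without KO replicate 4 and turned without WT replicate 1. Of 14200 genes tested, 126 rose and 164 fell, and DESeq2 called 700. The count was 154 without WT replicate 2 and 522 without KO replicate 4. Of 37 named genes 27 stayed past the threshold in every omission, and those lost were Myl1, Tnnc2, Myh2, Pik3ip1, Igf1r, Gabarapl1, Igfbp3, Timp1 and Mmp2, all without WT replicate 2 (adjusted p of up to 0.17), and Fmod without WT replicate 1 (0.206).

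In young Pax7-ROSAYFP mice of experiment 7, on day 4 after tamoxifen, 1 gene passed the threshold, Xist, at 348 and 173 CPM in the KO libraries and 1.7 and 1.82 CPM in the WT libraries. The sex of the mice and the genotype can therefore not be told apart in this comparison. Myog stood at 19.2 ± 8.89 against 1.5 ± 1.4 CPM (SD, n = 2), Foxo4 at 22.7 ± 7.09 against 57.3 ± 5.01 CPM and Spry1 at 212 ± 62.8 against 384 ± 6.83 CPM, each with an adjusted p of 0.7. The myogenic commitment list moved up with 0 called and 5 of 28 up adjusted over the list alone (adjusted p = 9.66e-06, but 0.586 with an estimated correlation). With 0 called, matrix genes (adjusted p = 9.59e-07, but 0.587 with an estimated correlation), endothelial (adjusted p = 3.81e-06, but 0.587 with an estimated correlation, with the direction turned and 0.868 without KO replicate 2), fibroblast (adjusted p = 0.00145, but 0.587 with an estimated correlation, and lost in 2 of 4 omissions, up to 0.44 without KO replicate 2) and pericyte markers (adjusted p = 0.0181, but 0.587 with an estimated correlation, and lost in 3 of 4, up to 0.487 without KO replicate 2) moved up. Immediate early genes (adjusted p = 9.26e-05, but 0.587 with an estimated correlation, and 0.06 without WT replicate 1), oxidative phosphorylation (adjusted p = 2.85e-05, but 0.596 with an estimated correlation, and 0.315 without WT replicate 1) and ribosomal proteins (adjusted p = 6.17e-05, but 0.6 with an estimated correlation, with the direction turned without WT replicate 1) moved down. DESeq2 called 37 genes. Without KO replicate 2 the count was 31 and without WT replicate 2 it was 2062, with the lone library assumed to vary like the pair left.

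In young mice on day 30 after tamoxifen in experiment 8, Foxo4 (1.91 ± 0.454 against 36.6 ± 3.74 CPM, SD, n = 2 KO and 3 WT) and Foxo1 fell. Txnip (51.4 ± 6 against 221 ± 14.4 CPM) and Cited2 (79.9 ± 2.51 against 275 ± 34 CPM), both on the list of FoxO targets, fell. Tnc rose from 97.5 ± 22.3 to 510 ± 18.4 CPM, the collagen gene Col1a1 from 62.2 ± 22.8 to 418 ± 55.3 CPM and Dlk1, a Notch ligand-like gene, from 9.17 ± 1.02 to 51.8 ± 15.2 CPM. Cd34, at 17.1 ± 0.913 against 134 ± 67.3 CPM, did not pass the test (adjusted p = 0.0887), nor did Spry1 (87 ± 19.5 against 297 ± 126 CPM). Of 13562 genes 8 rose and 6 fell, and DESeq2 called 178. The FoxO target list moved down with 2 of 42 called and 6 down adjusted over the list alone (adjusted p = 8.4e-13, but 0.232 with an estimated correlation), and the matrix list moved up with 3 of 45 called and 11 up adjusted over the list alone (adjusted p = 3.53e-13, but 0.254 with an estimated correlation). The fibroblast list moved up with it, with 1 of 28 called and 4 adjusted over the list alone (adjusted p = 4.04e-05, but 0.381 with an estimated correlation). Myofibre genes also moved up with 0 of 29 called (adjusted p = 7.26e-06, but 0.254 with an estimated correlation). So did Schwann and neural markers (adjusted p = 0.000121, but 0.691 with an estimated correlation, and 0.277 without WT replicate 1), cell cycle genes (adjusted p = 2.42e-06, but 0.378 with an estimated correlation) and senescence genes (adjusted p = 0.000121, but 0.381 with an estimated correlation) with 0 called. The quiescence list moved down (adjusted p = 0.0109, but 0.381 with an estimated correlation, and 0.295 without KO replicate 1) although its called members, the non-coding RNA Meg3 and Col5a3, rose, and adjusted over the list alone 4 rose and 7 fell. None of the 14 named genes stayed past the threshold in every omission. Without WT replicate 2 the count was 0 and the adjusted p was 0.442 for Foxo1, Foxo4, Txnip, Tnc and Col1a1 and 0.465 for Cited2, Dlk1, Meg3 and Col5a3, without WT replicate 3 the count was also 0, and without WT replicate 1 it was 26. The column names give different dates to WT and KO libraries, so that date and genotype cannot be told apart.

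In old mice of experiment 9, on day 4 after tamoxifen, edgeR called 0 genes between KO and WT (n = 2 each), with 1665 at an unadjusted p under 0.05 and 215 called by DESeq2. Cd34 stood at 49 ± 6.38 against 90.1 ± 60.6 CPM and Spry1 at 87.9 ± 6.71 against 188 ± 101 CPM. The list of FoxO targets moved down with 0 called (adjusted p = 0.0118, but 0.933 with an estimated correlation, and 0.735 without WT replicate 1). Also with 0 called, ribosomal proteins (adjusted p = 6.89e-12, but 0.933 with an estimated correlation), immediate early genes (adjusted p = 0.000567, but 0.79 with an estimated correlation) and oxidative phosphorylation (adjusted p = 1.08e-05, but 0.933 with an estimated correlation, and 0.97 without WT replicate 2) moved down. Matrix genes (adjusted p = 1.36e-06, but 0.933 with an estimated correlation, and 0.195 without WT replicate 1) moved up. Without WT replicate 1 the count was 3288, and without WT replicate 2 it was 1765, the lone WT library being assumed to vary like the KO libraries.

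In old mice at 22 months in experiment 10, Cd34 stood at 6.95 ± 8.1 CPM in KO and 132 ± 29.3 CPM in WT (SD, n = 3 each), a log2 fold change of -4.24 (SE 0.78, adjusted p = 0.041). The quiescence genes Tek (18.3 ± 5.69 against 115 ± 51.5 CPM), Cxcr4 (125 ± 45.1 against 524 ± 82.7 CPM) and Gpx3 (596 ± 290 against 2990 ± 744 CPM) fell. Higher in KO were the interferon-inducible Ifi202b (412 ± 169 against 0.359 ± 0.364 CPM), Dlk1 (244 ± 145 against 6.58 ± 1.74 CPM), the cytokine gene Il6 (107 ± 16.6 against 14.7 ± 7.83 CPM), Igfbp3 (143 ± 54.2 against 16.6 ± 12.2 CPM) and Tnc (1670 ± 1080 against 195 ± 84.8 CPM). Foxo1 (33.4 ± 12 against 48.7 ± 15 CPM) and Foxo4 (19.9 ± 6.42 against 34.7 ± 14.4 CPM) did not pass the test, so that the deletion itself was not detectable in these libraries.

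Of 32 senescence genes 3 rose and 0 fell, and adjusted over the list alone 15 rose and 1 fell (adjusted p = 1.63e-06). Of 45 matrix genes 4 rose and 14 rose adjusted over the list alone (adjusted p = 7.4e-10). Pericyte and smooth muscle markers moved up with 2 of 23 called and 7 adjusted over the list alone (adjusted p = 1.24e-05). The Schwann and neural list moved up with 0 of 23 called (adjusted p = 2.67e-08), but each of these lists had 0.547 with an estimated correlation. Immediate early genes moved up with 1 called (adjusted p = 0.0481, but 0.781 with an estimated correlation, and lost in 3 of 6 omissions, turned with 0.864 without WT replicate 3). The quiescence list moved down with 4 of 36 members, and 3 rose and 6 fell adjusted over the list alone (adjusted p = 0.0281, but 0.677 with an estimated correlation, and 0.101 without KO replicate 1). Ribosomal protein genes moved down with 47 of 56 adjusted over the list alone (adjusted p = 4.15e-24, but 0.547 with an estimated correlation). Of 13373 genes tested, 105 rose and 36 fell, and DESeq2 called 960. The count was 11 without KO replicate 3 and 339 without WT replicate 2. Of 28 named genes Ifi202b, Car3 and Dlk1 stayed past the threshold in every omission, and Cd34 reached an adjusted p of 0.159 without KO replicate 3. Tek (0.0961), Il6 (0.0862) and Igfbp3 (0.126) were also lost without KO replicate 3, Cxcr4 (0.0792) without KO replicate 2, and Gpx3 (0.104) and Tnc (0.115) without WT replicate 3.

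The KO calls of experiments 6, 8 and 10 overlapped. Experiments 6 and 10 shared 19 genes higher in KO, against 0.899 by chance (one-sided Fisher's exact test, adjusted p = 4.36e-19), among them Dlk1, Tnc, Nes, Igfbp3 and Ifi202b, and 15 genes lower in KO, against 0.443 (adjusted p = 5.24e-19), among them Cd34, Gpx3 and Tek. Experiments 6 and 8 shared Tnc, Dlk1 and Nes, higher in KO (chance 0.0724, adjusted p = 0.000156), and Foxo4, Foxo1, Ypel3 and Wbp1l, lower (chance 0.0742, adjusted p = 2.21e-06). Foxo1 and Foxo4 are targeted genes, so that this test of the lower genes was in part fixed by the design. Experiments 8 and 10 shared Dlk1, Nes and Tnc (chance 0.0626, adjusted p = 0.000126), and the shared lower gene was Wbp1l (chance 0.0167, adjusted p = 0.0553). No gene was called in opposite directions. As the deletion was not detectable in experiment 10, its overlaps cannot be put down to the loss of FoxO.

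The genes that parted the gates in experiment 4 were followed as a signature in the other experiments. Cd34 is part of the lower set. The higher set rose in CD34Lo of young cells in experiment 1 (median log2 fold change 1.48, adjusted p = 3.22e-06 with an estimated correlation), experiment 2 (1.11, 9.95e-07) and experiment 3 (1.44, 0.0204), and in geriatric (0.85, 0.0248) and adult (1.04, 0.000353) cells. In 21 day KO cells it rose, with 33 of 94 members up and 1 down (1.01, 0.00127), and the lower set fell (-0.98, 0.0101). In the later KO comparisons the higher set moved up with the preset correlation. With an estimated correlation its adjusted p was only 0.107, 0.119, 0.454 and 0.308 in experiments 7 to 10. With the preset correlation the adjusted p of the higher set was 0.989 in experiment 9 without WT replicate 1, where its direction turned, and up to 0.1 in experiment 10. In geriatric against young cells the lower set rose in CD34Hi (1.51, 0.0247) and CD34Lo (1.20, 0.0134). In adult against young cells, with an estimated correlation, the higher set fell in CD34Hi (adjusted p = 0.0155) and CD34Lo (0.000714), and the lower set rose in CD34Hi (0.0155) and CD34Lo (0.0083).

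**Figure D4:**
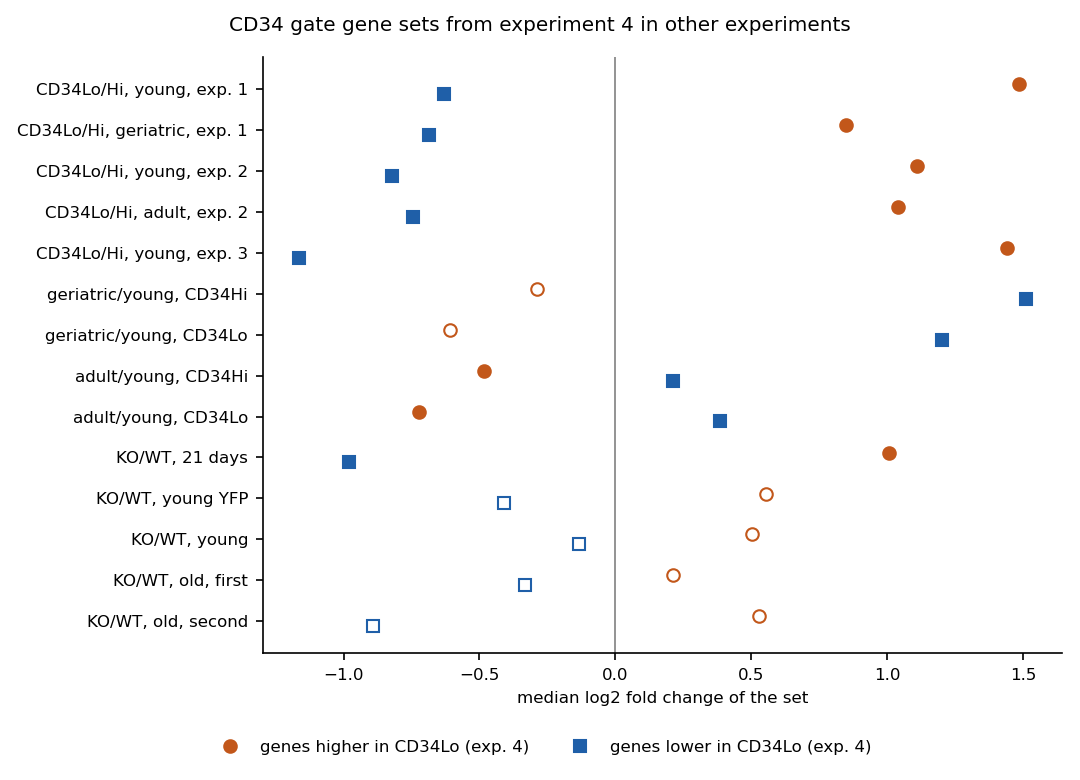
Median log2 fold change of the 96 genes higher and the 17 genes lower in CD34Lo of experiment 4, in each comparison of the other experiments, filled where the adjusted p with an estimated correlation was under 0.05. At 21 days the higher set had a median of 1.01 and the lower set of -0.98 in KO against WT.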

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

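The tests of other splits of the libraries and those of immune cells, female cells, fibroblasts and myofibre RNA were chosen after the results were seen. In the tests of immune cells, fibroblasts and myofibre RNA, CPM are counts over the unscaled library total, without TMM.

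Libraries far from the others of their group were sought in 176 groups of values, of which 12 held 1. Chance sets apart about 1 in 20 groups. Among libraries labelled KO at 8 days, replicate 3 had Cd34 at 125 CPM (others 19.1 to 26.2), Foxo1 at 72.9 CPM (2.84 to 18.8) and Foxo4 at 132 CPM (1.68 to 8.34). Replicate 4 of that group had 18.3 M total counts (41 to 51.3). In experiment 2, young CD34Lo replicate 4 had 8.68 percent of its counts in the 10 most abundant genes (5.34 to 5.43) and Hes1 at 68.9 CPM (5.1 to 13.1), and young CD34Hi replicate 3 had Foxo1 at 32.4 CPM (24.2 to 25.3). In experiment 4, CD34Hi replicate 1 had Pax7 at 30.7 CPM (17 to 19.3), CD34Lo replicate 3 had Myog at 698 CPM (1450 to 1580) and CD34Lo replicate 2 had Cdkn1b at 12.8 CPM (8.46 to 9.1). Cdkn1b was at 107 CPM in 21 day KO replicate 2 (84.6 to 87.7), and Mki67 at 30.8 CPM in young CD34Hi replicate 4 of experiment 1 (0 to 3.79).

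The 6 libraries labelled KO at 8 days entered no comparison. Their median was 9.05 CPM for Foxo1 (2.84 to 72.9) and 5.12 CPM for Foxo4 (1.68 to 132). The effect of age differed between the gates of experiment 2 for 62 genes by the interaction test.

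The interferon and antigen presentation genes that rose in geriatric cells were weighed against immune cells, which the CD45 gate was set to remove. The immune marker list summed to 43.6 CPM in geriatric and 15.7 CPM in young CD34Hi and to 50.3 and 47.2 CPM in CD34Lo, while the interferon list rose from 3010 to 9140 CPM and from 3120 to 9130 CPM. The larger ratio of the rises was 0.00454, which argues against immune cells as the source of the summed rise. The abundant B2m held most of it, so immune cells stay open for less abundant genes. Female cells are argued against as well, since without the Xist-holding libraries the median fold change of the list was larger (lower ratio of medians 1.19). Age itself, and a response of the animals or cells to something not given in the labels, stay open and were not tested.

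Of 28 fibroblast markers 8 were called higher in adult CD34Lo than adult CD34Hi of experiment 2 (adjusted p = 0.000116 for the list, but 0.499 with an estimated correlation), and fibroblasts in the sorted cells are a candidate source, although the Sca-1 gate was set to remove many such cells. The 12 list members under 20 CPM in adult CD34Hi had a median log2 fold change of 1.03, from -0.47 for Thy1 to 2.72 for Clec3b. Choosing them by a low CD34Hi level favours a rise, so this median cannot decide. The abundant Dcn rose from 823 to 3540 CPM, but the log2 fold changes of the abundant Gsn (-0.07), Dpt (-0.64) and Mmp2 (-1.3) were not above 0. Pdgfra (0.36), Ly6a (0.64) and Fap (0.24) were not called. A change within the satellite cells, with several of these genes expressed by both cell types, stays open and was not tested.

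The myogenic genes of CD34Lo cells in experiment 4 were weighed against RNA of broken myofibres. Such RNA would bring the most abundant myofibre transcripts. The median rise of Ckm, Acta1, Myh4, Pvalb and Mylpf was 0.00591 of that of Myog, and only Acta1 rose by a like amount (0.968), which argues against myofibre RNA as the source of Myog. Cells on the way to differentiation inside the gate may be the source, a hypothesis that came from these data and was not tested.

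Other splits of the same libraries were compared with the real one. Only the real one of 35 splits gave as many genes for young CD34Lo against CD34Hi in experiment 1 (3 genes, highest other split 0) and experiment 2 (30, 0). The same held for adult cells (388, 0), geriatric against young CD34Hi (2858, 0) and CD34Lo (1477, 794), adult against young CD34Hi (27, 1) and KO at 21 days (290, 3). A share of 1 in 35 is the lowest these splits can give, and it was not adjusted over the comparisons. It argues against chance only for each comparison taken alone. The 3 calls of young cells in experiment 1 were also lost in every omission. There 5 of 8 libraries were most like the library of their own number, so a pairing is possible. The interaction in experiment 2 (62, highest other 16) was the highest of 100 splits drawn. Those splits shuffled age within each gate, which also removes the age effect shared by the gates. They therefore cannot decide whether the interaction itself is due to chance. In geriatric CD34Lo against CD34Hi, 25 of 35 splits gave as many as the real 1 gene, and the split of replicates 1 and 2 against 3 and 4, along Xist, gave 1599, which points to a structure of the samples. Libraries of the same number resembled each other there and in CD34Lo and CD34Hi of experiment 4, so that only the 8 splits that part every pair are like the real one, too few for a share under 0.05. Among these the highest other was 2 for the geriatric gates and 0 in experiment 4 (113 genes, 1 of 35 splits, highest other 0). Chance is not excluded for adult against young CD34Lo (209 genes, 2 of 35 splits, highest other 559), nor for CD34Med against CD34Hi (27 genes, 2 of 35, highest other 141). In both, a split that calls more than 2 times the real count points to a structure of the samples that the groups do not give. A real count of 0 is reached by every split, so that the splits decide nothing for the interaction in experiment 1 (100 of 100, highest other 3831) and for CD34Lo against CD34Med (35 of 35, highest other 0). In experiment 10 the 10 splits are too few for a share under 0.05 (141 genes, 1 of 10, highest other 0).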

How the results depend on the processing

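The Xist and column number alternatives and the one without Malat1 and Rn45s were chosen after seeing the data. Counts of changed genes kept within 1.5 times with RLE scaling in all 19 comparisons and without Malat1 and Rn45s in all 10 run. Of the named genes past the threshold, all 287 kept direction and call with DESeq2 and with RLE, and 284 with no filter. With only the libraries of the groups compared 24 of 188 were lost, and with the block on consecutive library numbers 12 of 36, among them Cd34 in both cases, while leaving out 1 library kept 1616 of the gene and library pairs and lost 485. Where a result moved, the cause was not tested. The signature from experiment 1 was not run, since it had fewer than 5 genes, the block on library numbers could not be formed in experiment 4, a pseudocount does not apply to counts, and KO against WT at 8 days was not run. Few counts limit the test for genes such as Foxo3 and Foxo4 in experiments 1, 2 and 4.

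DESeq2 counts were, for CD34Lo against CD34Hi, 21 in young, 202 in geriatric (experiment 1), 108 in young and 811 in adult cells (experiment 2), 261 in experiment 3 and 256 in experiment 4, 67 for CD34Med against CD34Hi and 6 for CD34Lo against CD34Med. For age they were 2461 in geriatric CD34Lo, 201 in adult CD34Hi and 535 in adult CD34Lo, with 10 and 199 for the interactions. For KO they were 700, 37, 178, 215 and 960 in experiments 6 to 10.

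With no filter the counts were 5 in young and 0 in geriatric cells of experiment 1, 337 in experiment 3, and 34, 119 and 455 for KO in experiments 7, 8 and 10. With only the libraries compared they were 36, 0, 5 and 798 for CD34Lo against CD34Hi in young and geriatric (experiment 1) and young and adult cells (experiment 2), 200 and 137 for adult age in CD34Hi and CD34Lo, and 12 for CD34Med. With the block on library numbers they were 5, 0, 6 and 154 for the same 4 gate comparisons, with column numbers 215 in experiment 4 and 3 in experiment 7, and 35 with crossed numbers. Without the Xist-holding libraries they were 221, 5070, 4328 and 42 for geriatric gates, geriatric CD34Hi, geriatric CD34Lo and the interaction, and the lists past the threshold were 0 for the gates and 2 for the interaction.

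With an estimated correlation the number of lists past the threshold was 2, 0, 0, 0 and 0 in experiment 1 (young gates, geriatric gates, age in CD34Hi, age in CD34Lo, interaction), 1, 0, 1, 0 and 0 in experiment 2, 0 in experiment 3, 2 in experiment 4 (CD34Lo against CD34Hi) and 2 (CD34Lo against CD34Med), 2 at 21 days and 0 in experiments 7 to 10. The signature lost its call there for the higher set in geriatric CD34Lo (0.106), the interaction of experiment 1 (0.091) and KO of experiments 7 (0.107), 8 (0.119), 9 (0.454) and 10 (0.308), and for the lower set in experiments 7 (0.263), 8 (0.149), 9 (0.243) and 10 (0.113).

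With DESeq2 calls the shared genes higher in CD34Lo, with the number by chance, were 8 (0.0616), 8 (0.108), 14 (0.232), 10 (0.233), 17 (0.572) and 32 (0.982) in experiments 1 and 2, 1 and 3, 1 and 4, 2 and 3, 2 and 4, and 3 and 4, and those lower 21 (0.873), 13 (0.272) and 29 (0.821) in the last 3. For KO, higher and lower, they were 8 (0.391) and 8 (0.477) in experiments 6 and 7, 31 (1.57) and 63 (3.17) in 6 and 8, 5 (3.04) and 5 (1.57) in 6 and 9, and 79 (14.1) and 89 (8.01) in 6 and 10. They were 4 (0.115) and 8 (0.175) in 7 and 8, 0 (0.199) and 2 (0.0809) in 7 and 9, 7 (0.738) and 5 (0.401) in 7 and 10, 1 (1.34) and 8 (0.474) in 8 and 9, 34 (3.68) and 48 (2.9) in 8 and 10, and 26 (9.1) and 8 (1.33) in 9 and 10.

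Leaving out 1 library at a time gave counts, lowest to highest, of 0 to 0 (young gates), 0 to 19 (geriatric gates), 1831 to 3106 (age in CD34Hi), 680 to 2858 (age in CD34Lo) and 0 to 1 (interaction) in experiment 1. In experiment 2 they were 5 to 75, 156 to 403, 4 to 21, 114 to 538 and 26 to 146 in the same order. They were 1 to 104 in experiment 3, 65 to 119, 12 to 39 and 0 to 0 in experiment 4, and 154 to 522, 31 to 2062, 0 to 26, 0 to 3288 and 11 to 339 in experiments 6 to 10. Lists past the threshold numbered 2 to 6 for geriatric gates, 2 to 5 for the interaction of experiment 1, 5 to 10 for young gates of experiment 2, 3 to 8 and 3 to 6 for CD34Lo and CD34Med against CD34Hi, 5 to 10 in experiment 7 and 4 to 8 in experiment 9. Adjusted p of the signature ran from 0.0361 to 0.43 (higher set, interaction of experiment 2), 4.48e-07 to 0.0797 (lower, experiment 7), 3.93e-09 to 0.536 (lower, 8), 1.18e-07 to 0.989 (higher, 9, turned without WT replicate 1), 3.43e-04 to 0.53 (lower, 9) and 2.76e-05 to 0.1 (higher, 10).

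Direction turned in at least 1 omission for Myog in experiment 9 (log2 fold change -1.13 to 1.88) and for these lists, with the range of adjusted p. In experiment 2 they were oxidative phosphorylation (2.76e-11 to 0.0163) and ribosomal proteins (4.65e-09 to 0.11) in young gates, immediate early genes (9.81e-04 to 0.99) and oxidative phosphorylation (2e-12 to 0.518) in adult CD34Lo, and immune (0.00103 to 0.899), oxidative phosphorylation (9.92e-11 to 0.819) and ribosomal genes (1.46e-11 to 0.819) in the interaction. The others were immune genes in CD34Lo against CD34Med (2.6e-07 to 0.934), pericyte (2.86e-06 to 0.182) and Schwann genes (7.56e-06 to 0.494) at 21 days, endothelial (1.01e-50 to 0.868) and ribosomal genes (8.73e-33 to 0.00156) in experiment 7, and immediate early genes in experiment 10 (0.00261 to 0.864).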

Other observations

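The tests of genes lower or higher in KO in geriatric cells were set out before their results were seen, and the gene lists below were fixed with the others.

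Beyond the groups described above, genes of other cell types and pathways moved in some comparisons. In KO cells at 21 days 3 senescence genes rose, among them Tnf (7.14 ± 1.87 against 0.619 ± 0.223 CPM), with 3 up adjusted over the list alone (adjusted p = 0.00225, but 0.747 with an estimated correlation). The pericyte gene Rgs4 fell from 68.4 ± 8.92 to 24.1 ± 4.34 CPM. Pericyte and smooth muscle genes moved up in geriatric CD34Hi, with 6 of 16 up and 7 adjusted over the list alone (adjusted p = 0.000555, but 0.303 with an estimated correlation), as they did in geriatric CD34Lo (adjusted p = 0.00392, but 0.295 with an estimated correlation). Notch3, which satellite cells also express, rose from 14.4 ± 2.43 to 87.5 ± 40.7 CPM. The CD31 and Sca-1 gates were set to remove endothelial cells. In geriatric CD34Lo the Schwann and neural list moved up with 3 of 11 (adjusted p = 0.0229, but 0.412 with an estimated correlation, and 0.207 without geriatric replicate 2), with Scn7a at 51.6 ± 63 against 1.75 ± 1.34 CPM. The Notch pathway did not pass in geriatric cells (adjusted p = 0.488 in CD34Hi, 0.618 in CD34Lo), nor did the cell cycle (0.185 and 0.488) or the immune list (0.14 and 0.265).

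Whether the genes that change at 21 days without FoxO are those that change with geriatric age was tested as a hypothesis. The 162 genes lower in KO, without Foxo1 and Foxo4 themselves, of which 158 were measured, moved up in geriatric CD34Hi with the preset correlation (camera p = 0.0046, not adjusted, median log2 fold change 0.38) but not with an estimated correlation (camera p = 0.277, adjusted p = 0.554 over the 4 tests), with 44 up and 14 down. In CD34Lo the same set moved up with the preset correlation (camera p = 5.41e-05, not adjusted, median 0.56), and had camera p = 0.122 with an estimated correlation (adjusted p = 0.488), with 35 up and 8 down. Both moves were opposite to the change in KO. Of the 126 genes higher in KO 84 were measured, and for them the camera p with an estimated correlation was 0.461 in CD34Hi (adjusted p = 0.615) and 0.96 in CD34Lo (adjusted p = 0.96). None of the 4 tests passed the threshold with an estimated correlation, so the hypothesis was neither borne out nor excluded, and the geriatric libraries also differ from the young ones in Xist.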
